A study of Mus musculus with 12 samples.

How the data were processed

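RNA was sequenced from immunopanned cells of the injured mouse cortex in 12 libraries, 3 in each of 4 groups. The groups were the astrocyte fraction (cells bound to a plate coated with antibody against ACSA-2) and the immune fraction (cells bound to a secondary-antibody plate and a CD45 plate), each from Sema4B+/- and Sema4B-/- mice. Tissue was taken 12 h after injury. Per the labels, reads were processed with cutadapt, STAR, HTSeq and DESeq2 on genome build GRCm38, with no versions given and no annotation named.

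The deposited tables, 1 per fraction, each held 20776 genes. Per the file headers, the columns used here were raw counts, that is, whole numbers of reads per gene with no normalization. The same deposited tables gave the authors' log2 fold change of knockout over heterozygote. The deposited p-value columns held the authors' p-values and adjusted p-values, whose adjustment method was not stated. A deposited score per gene, the highest raw count of any library, was used with the authors' thresholds for an adjusted p of 0.05, an absolute log2 fold change of 1 and a highest count of 30. The deposited column for genes passing those thresholds was empty, so passing genes were counted from the 3 thresholds. The 12 normalized-count columns were not used here. The numbering of the sample titles and of the table columns differed, so libraries were treated as replicates of their group, with no further mapping, and are named below by the number in the deposited column head. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries.

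Total reads ranged from 13530229 to 15993564 in the astrocyte libraries and from 11111965 to 15135960 in the immune libraries. A floor of 3 reads corresponded to 0.188 to 0.222 CPM (here reads over the unscaled library total) in the astrocyte libraries and to 0.198 to 0.270 CPM in the immune libraries. Floors cover counting error only. The interval of a score is 2 standard errors of the spread between libraries, and that of a share of genes is exact binomial (Clopper-Pearson) and treats genes as independent. Replicates were checked for copies of a library. Over the 12 pairs within groups and genes with at least 20 reads per pair, the mean chi-square per gene was 10.9 to 79.9. Coordinates came from GENCODE mouse release 21, which held 20740 of the gene identifiers. The 51 identifiers that shared a symbol were kept apart by identifier.

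Knockout was compared with heterozygote within each fraction by the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with TMM scaling, filterByExpr (count minimum 10, total minimum 15) and a robust fit. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Levels were CPM on TMM-scaled library totals of the fit at hand, except for sex-linked transcripts, which were scaled to the unscaled total. A fit of all 12 libraries tested the difference of the genotype effect between the fractions, and the astrocyte against the immune fraction in heterozygotes. Genes tested numbered 15648 in the immune fraction, 15468 in the astrocyte fraction and 16880 in the fit of 12 libraries. The test was two-sided throughout.

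The 29 gene lists were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives, except those stated in the closing section as chosen later. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. The alternatives were camera with an estimated correlation and fry. List scores were means of log2(CPM + 0.5). The mural score was that mean over 5 genes, Pdgfrb, Abcc9, Kcnj8, Rgs5 and Vtn, and the neuron score over the neuron list. Comparisons of a single value used two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

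The rule named Sema4b, and up to 10 genes per direction past the threshold with a mean of at least 5 CPM and no overlap between groups. Where fewer than 5 genes of a direction qualified, it named the 5 with the lowest p and at least 5 CPM. It also named up to 4 members with the lowest p of each list past its threshold and at most 2 of any other list. For the difference between fractions it named the 5 genes with the lowest p in each direction. All genes named by the rule entered the tests of alternatives, and the text gives examples from them.

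The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, other count filters, 1 surrogate variable (sva 3.50.0), a sex term, 1 fit of all 12 libraries, other thresholds and leaving out each library. The edgeR test was tested on simulated data with 200 changed genes. These were drawn only from genes above a minimum mean read count, and all genes were simulated independently of each other. In the immune fraction it recovered 1.00% of genes changed 1.5-fold, 44.5% of those changed 2-fold and 95.5% of those changed 4-fold, with 6, 9 and 15 false calls beside 2, 89 and 191 recovered genes. In the astrocyte fraction it recovered 12.0%, 81.0% and 98.0%, with 6, 14 and 18 false calls beside 24, 162 and 196 recovered genes. The share of false calls therefore lay above the threshold of 0.05. With no gene changed there were 0 calls in both fractions. Pseudogene sequence was compared with annotated transcripts by shared 31-base words. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.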

Results

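The series measured gene expression in 2 cell fractions of the mouse cortex 12 h after an injury, in mice with 1 or no intact copy of Sema4b, a transmembrane semaphorin. A square of 3 mm around the wound was dissociated and immunopanned into an astrocyte and an immune fraction. Each of the 4 groups of fraction and genotype held 3 libraries, with 11111965 to 15993564 reads per library. Values after ± are SD over n = 3 libraries for levels in CPM, and standard errors for log2 fold changes (knockout over heterozygote unless stated). Levels are TMM-scaled CPM from the fit of the comparison at hand, so the fit of all 12 libraries and that of a fraction give the same libraries slightly different values.

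The comparison of the fractions in heterozygotes shows what each fraction held. Astrocyte markers were higher in the astrocyte fraction for 18 of 18 genes, with a median of 44.0-fold. The glutamate transporter gene Slc1a2 stood at 11608 ± 998 CPM there and at 228 ± 21.7 CPM in the immune fraction. Microglia markers were higher in the immune fraction for 14 of 15 genes (median 25.1-fold), neutrophil markers for 17 of 17 (48.0-fold), monocyte markers for 13 of 14 (41.8-fold) and border macrophage markers for 11 of 12 (68.9-fold). Csf1r, the receptor microglia need for survival, had 3147 ± 489 CPM in the immune and 88.5 ± 18.8 CPM in the astrocyte fraction.

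Other cell types were present as well. Markers of endothelial and mural cells were higher in the astrocyte fraction for 15 of 18 genes (12.5-fold), and oligodendrocyte markers for 12 of 12 (7.49-fold). Of 16 neuron markers, 6 were higher in the immune fraction and 0 in the astrocyte fraction by edgeR, and the other 10 did not pass. The synaptic gene Snap25 had 1806 ± 617 CPM in the immune and 1009 ± 268 CPM in the astrocyte fraction, with an adjusted p of 0.0618 by edgeR. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 5064 genes were higher and 5107 lower in the astrocyte fraction. That test treats the libraries of the 2 fractions as independent, which the labels do not establish.

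Sema4b itself (ENSMUSG00000030539, GRCm38 chromosome 7, 80186841 to 80226527) was mainly a transcript of the astrocyte fraction. In the fit of all 12 libraries, heterozygotes had 80.2 ± 26.7 CPM there and 7.60 ± 1.41 CPM in the immune fraction, a log2 difference of 3.40 ± 0.43 (edgeR adjusted p = 1.34e-05). Genes of plexin B receptors, which bind class 4 semaphorins, were divided. Plxnb1 was higher in the astrocyte fraction, at 459 ± 53.6 against 10.7 ± 4.02 CPM, and Plxnb2 in the immune fraction, at 345 ± 56.0 against 91.7 ± 3.03 CPM.

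Knockout libraries still held Sema4b reads. In the fit of the astrocyte fraction the level was 75.0 ± 24.8 CPM in heterozygotes and 40.7 ± 13.5 CPM in knockouts, a log2 fold change of -0.88 ± 0.29 (edgeR adjusted p = 0.930). In that of the immune fraction it was 7.91 ± 1.25 and 3.14 ± 2.38 CPM, a log2 fold change of -1.32 ± 0.48 (edgeR adjusted p = 0.270). The knockout libraries lay below all heterozygous ones in both fractions, but neither difference passed the threshold. The labels do not say which part of the gene was altered, and the tables count whole genes.

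**Figure D1:**
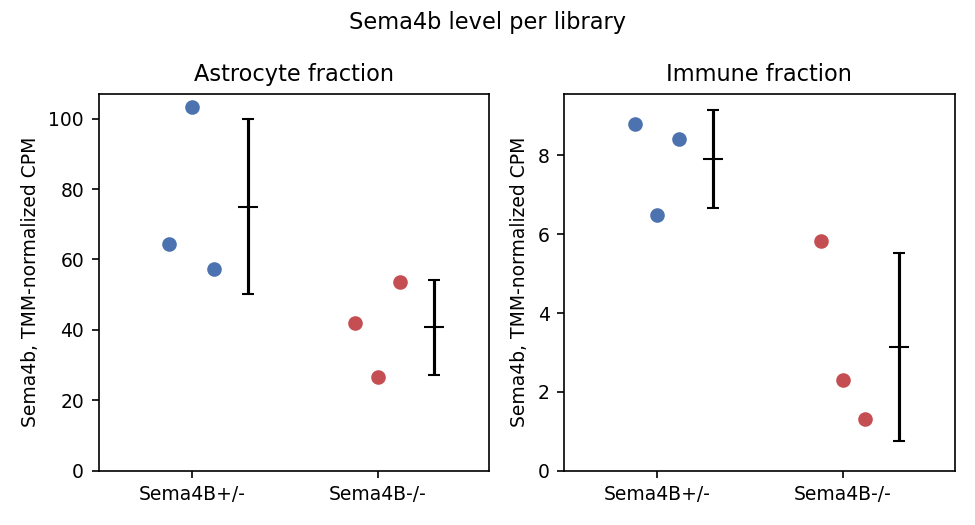
Sema4b in TMM-normalized CPM (vertical axes, from 0) for each library of both genotypes, astrocyte fraction left and immune fraction right, with bars for the mean ± SD of 3 libraries. Knockout libraries lay below the heterozygous ones in both fractions, and their means were 40.7 and 3.14 CPM.

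The genotype comparison in the immune fraction asks how loss of Sema4b alters the cells that gather at the wound. As groups, genes of microglia and infiltrating myeloid cells lay lower in knockout libraries, and genes of neurons and vessels lay higher. All 15 microglia markers had negative fold changes (median log2 fold change -0.62, camera adjusted p = 7.21e-09), as did 17 of 17 neutrophil markers (-0.83, 3.93e-07), 14 of 14 monocyte markers (-0.82, 1.43e-06) and 12 of 12 border macrophage markers (-0.58, 6.54e-05). All 4 calls were lost with an estimated correlation, each at adjusted p = 0.722. The scores of neutrophil and of monocyte markers overlapped between the genotypes (exact permutation p = 0.2 each). Knockout immune libraries also held more reads, 13595280 to 15135960 against 11111965 to 13190826, and a larger share in protein-coding genes, 98.0 ± 0.184% against 97.7 ± 0.0992% (exact permutation p = 0.1 each). The purinergic receptor gene P2ry12 went from 251 ± 73.5 to 153 ± 11.9 CPM, and P2ry13 from 318 ± 39.2 to 198 ± 43.5 CPM. The neutrophil chemokine receptor gene Cxcr2 went from 89.8 ± 39.2 to 47.8 ± 13.4 CPM, the monocyte gene Ccr2 from 31.5 ± 11.7 to 16.0 ± 7.14 CPM, and the macrophage mannose receptor gene Mrc1 from 169 ± 10.2 to 101 ± 28.5 CPM.

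Genes of inflammatory signalling lay lower as well. Negative fold changes were found for 23 of 26 cytokine and chemokine genes (median log2 fold change -0.46, camera adjusted p = 0.000142) and for 22 of 24 NF-kappaB target and feedback genes (-0.45, 5.13e-06). Both calls were lost with an estimated correlation, at adjusted p = 0.794 and 0.738. The scores of the 2 lists overlapped between the genotypes (exact permutation p = 0.3 and 0.2). Knockout library 9 stood at 0.18 and -0.072 relative to the heterozygous mean, and heterozygous library 3 at -0.48 and -0.32. Osm, which encodes the cytokine oncostatin M, went from 387 ± 74.1 to 215 ± 82.5 CPM, and Tnfaip3, a brake on NF-kappaB, from 1555 ± 215 to 751 ± 390 CPM. Immediate early and heat shock genes were negative in 21 of 25 (-0.40, 4.31e-05; adjusted p = 0.722 with an estimated correlation), with Atf3 at 955 ± 101 and 519 ± 96.5 CPM and Jun at 587 ± 150 and 302 ± 108 CPM.

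Further lists of myeloid function lay on the same side. MHC class II presentation was negative in 12 of 12 genes (median log2 fold change -0.46, camera adjusted p = 0.00240), disease-associated microglia genes in 21 of 25 (-0.38, 0.00314) and alternative activation genes in 15 of 19 (-0.35, 0.00414). With an estimated correlation these calls were lost, at adjusted p = 0.722, 0.794 and 0.738. The exact permutation p of the list scores was 0.3, 0.4 and 0.3. Spp1, a secreted phosphoprotein gene, had 188 ± 119 and 106 ± 20.7 CPM. Trem2, a microglial lipid receptor gene, had a log2 fold change of -0.48 ± 0.19, which turned to 0.13 when libraries were scaled to microglia markers, a scaling that moved the median of all genes by 0.62. Ank at 0.59 ± 0.21 and Pparg at 0.71 ± 0.26 ran opposite to their lists.

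Neuron markers had positive fold changes in 16 of 16 genes (median log2 fold change 0.58, camera adjusted p = 2.75e-06), and 3 passed when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.722). Slc17a7, the vesicular glutamate transporter gene of excitatory neurons, had 285 ± 65.6 and 645 ± 230 CPM, and Grin2b, an NMDA receptor gene, 74.8 ± 10.6 and 122 ± 16.7 CPM. Endothelial and mural markers were positive in 17 of 17 (0.95, 0.00166) and astrocyte markers in 18 of 18 (0.51, 0.0197), calls lost with an estimated correlation at adjusted p = 0.802 and 0.819. The exact permutation p of their scores was 0.5 and 0.6. The mural gene Abcc9 rested on part of the knockout libraries, at 6.67 ± 6.83 CPM against 0.910 ± 0.0149 CPM. Cholesterol synthesis genes were positive in 19 of 22 (0.27, 0.00848; adjusted p = 0.722 with an estimated correlation). Semaphorin and plexin genes were positive in 22 of 32 (0.48, 0.0113; adjusted p = 0.805 with an estimated correlation), with 4 past the threshold adjusted over the list alone, and Sema7a had 47.6 ± 8.18 and 84.9 ± 8.58 CPM.

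Among the genes with the lowest p, Scn2b, a sodium channel subunit gene, had a log2 fold change of 1.13 ± 0.19, Tenm4 of 1.21 ± 0.21, Sgpp2 of 1.53 ± 0.30 and the calcium channel gene Cacna1c of 1.13 ± 0.22. On the other side were Cd33, an inhibitory myeloid receptor gene, at -0.93 ± 0.18, Mob3c at -0.81 ± 0.17, Kif2c at -1.04 ± 0.23, Klhl6 at -0.77 ± 0.17 and the gene model Gm10800 at -2.19 ± 0.43.

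By edgeR, 0 genes were higher and 0 lower at the threshold among 15648 tested. The lowest adjusted p was 0.227, and 2284 genes had an unadjusted p under 0.05, 1517 of them higher and 767 lower. That count was 1220 (377 lower) without heterozygous library 1, 1316 (315 lower) without heterozygous library 5 and 830 with the neuron score as a covariate. Every knockout library had a higher neuron score than every heterozygous one, so this covariate could take up part of the genotype difference. Without knockout library 11 the count was 1875 (361 lower), and without heterozygous library 3 it was 2986 (1209 lower). Scaled to microglia markers it was 6406, 6399 of them higher. In the fit of all 12 libraries it was 3418, with 1647 higher and 1771 lower. DESeq2 called 378 genes higher and 68 lower, and limma-voom called 0 and 0. The authors' deposited table listed 167 higher and 19 lower at an adjusted p of 0.05, of which 102 and 9 passed all 3 of their thresholds. Of these 186 genes, 183 were among the 446 DESeq2 called here, and all 185 that edgeR tested had the same sign. Groups did not overlap for 3117 genes, or 19.9%, where chance gives 10%.

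Of the 29 lists, 10 were called lower and 5 higher by camera, and 0 kept the call with an estimated correlation (adjusted p = 0.722 to 0.819) or by fry (lowest adjusted p = 0.542). Without heterozygous library 1 the camera adjusted p was 0.108 for astrocyte markers and 0.138 for disease-associated microglia genes. Without knockout library 7 it was 0.332 for astrocyte markers and 0.483 for semaphorin and plexin genes, and without knockout library 9 it was 0.648 for astrocyte and for endothelial and mural markers. Without knockout library 11 it was 0.1001 for disease-associated microglia genes and 0.0869 for alternative activation genes.

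Other settings also ended list calls in the immune fraction. With the neuron score as a covariate, chosen after the data were seen, NF-kappaB (camera adjusted p = 0.615), alternative activation (0.497) and disease-associated microglia genes (0.0896) turned direction, and cytokine genes turned positive (0.0457). Border macrophage markers and MHC class II genes then stood at 0.206 each. Neuron scores relative to the heterozygous mean were 0.32 to 1.02 in knockout and -0.46 to 0.27 in heterozygous libraries. This covariate could therefore take up the genotype effect, and these changes do not show whether the inflammatory lists followed neuron RNA. With limma-voom, cytokine and disease-associated microglia genes stood at 0.0908 and alternative activation genes at 0.105, and scaled to microglia markers endothelial and mural markers stood at 0.0579.

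The remaining 14 lists did not pass. Camera adjusted p was 0.0564 for A2 and 0.298 for A1 reactive astrocyte genes, 0.508 for pan-reactive genes, 0.0824 for oligodendrocyte and 0.369 for oligodendrocyte precursor markers, and 0.0897 for interferon-stimulated genes. It was 0.298 for genes around Sema4b, 0.369 for red blood cell transcripts, 0.474 for proliferation, 0.611 for matrix, 0.786 for glycolysis, 0.788 for mitochondrially encoded, 0.927 for sex-linked and 0.694 for lymphocyte genes. The lymphocyte list had a median of 0.12 while its mean and its test were negative, and the mitochondrial list a median of 0.0059 with a negative mean and test.

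**Figure D2:**
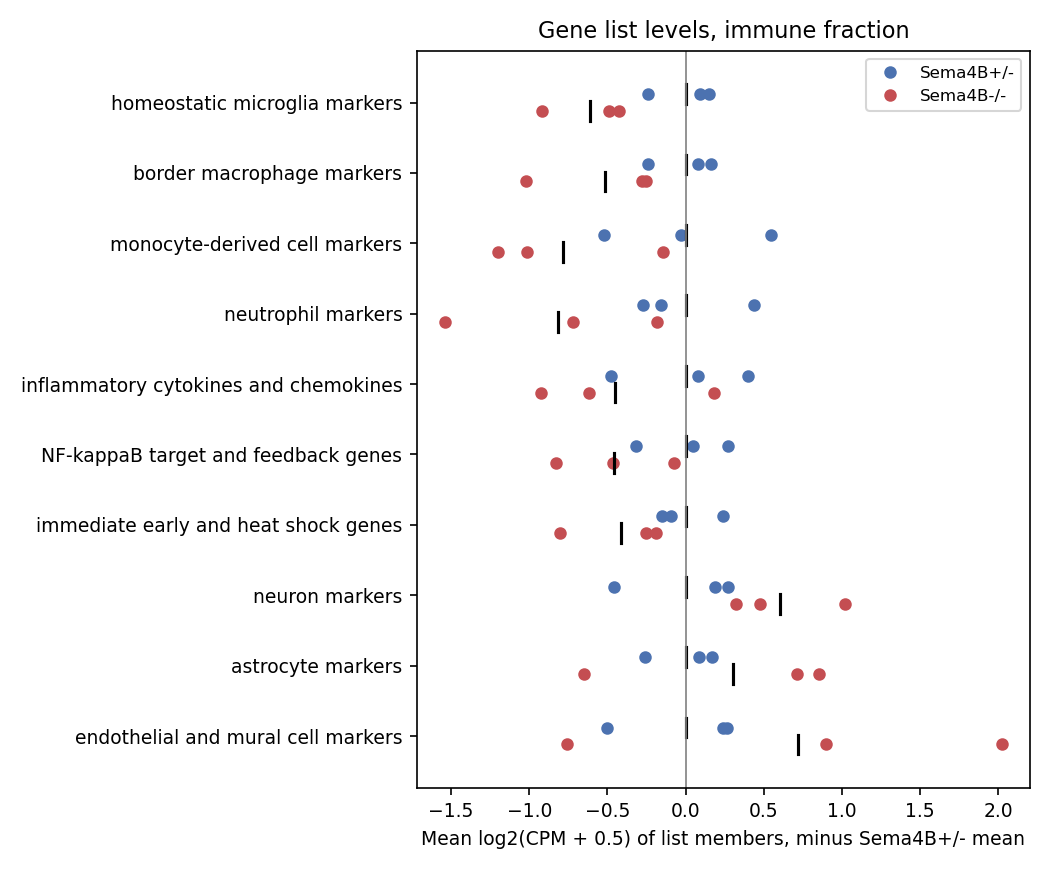
Mean log2(CPM + 0.5) of each list's members per immune library (horizontal axis, relative to the heterozygous mean), with dots for libraries and black ticks for group means of 3 libraries. Myeloid lists had lower means in knockouts, with overlap between the groups for the monocyte, neutrophil, cytokine and NF-kappaB lists. The knockout libraries were widely spread for endothelial and mural and for astrocyte markers.

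In the astrocyte fraction the same comparison asks how loss of Sema4b alters the reactive astrocyte. Genes of astrocyte reactivity, matrix and vessel walls had mostly negative fold changes in knockouts, though the scores of these lists overlapped between the genotypes. Negative fold changes were found for 11 of 13 pan-reactive genes (median log2 fold change -0.24, camera adjusted p = 8.79e-05), 11 of 12 A2 genes (-0.34, 0.000204) and 11 of 12 A1 genes (-0.17, 0.0322). With an estimated correlation these calls were lost, at adjusted p = 0.520, 0.520 and 0.536. Cp, which encodes the copper carrier ceruloplasmin, had 220 ± 31.1 CPM in heterozygotes and 142 ± 22.9 CPM in knockouts and was the 1 pan-reactive gene that passed when adjusted over the list alone. Steap4 had 119 ± 34.6 and 83.6 ± 1.92 CPM, and the A2 gene Tgm1 had 120 ± 8.93 and 94.7 ± 3.91 CPM.

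Matrix and scar genes were negative in 20 of 28 (median log2 fold change -0.30, camera adjusted p = 4.21e-05, and adjusted p = 0.520 with an estimated correlation), with the basement membrane collagen gene Col4a1 at 230 ± 35.4 and 158 ± 39.4 CPM. Endothelial and mural markers were negative in 17 of 18 (-0.43, 0.000216; adjusted p = 0.642 with an estimated correlation), and the pericyte receptor gene Pdgfrb had 211 ± 9.31 and 140 ± 28.1 CPM. The score of that list differed by only -0.20, with a standard error of 0.45 (exact permutation p = 0.7). Knockout libraries lay at -0.33 to -0.0050 relative to the heterozygous mean, within the heterozygous range of -0.78 to 0.72. NF-kappaB genes were negative in 21 of 24 (-0.22, 9.83e-05) and cytokine genes in 20 of 25 (-0.20, 0.00523), with Tnfaip3 at 46.4 ± 4.60 and 34.7 ± 7.44 CPM. These calls were lost with an estimated correlation, at adjusted p = 0.520 and 0.803. Semaphorin and plexin genes were negative in 27 of 32 (-0.14, 0.000378), and red blood cell transcripts in 5 of 5 (-0.72, 1.88e-05), calls lost with an estimated correlation at adjusted p = 0.319 and 0.520.

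Mitochondrially encoded transcripts were positive in 9 of 9 (median log2 fold change 0.41, camera adjusted p = 3.63e-11), and 1 of them passed when adjusted over the list alone. Their estimated correlation was 0.892, and with it the call was lost (adjusted p = 0.520). The ribosomal RNA gene mt-Rnr1 had 1025 ± 283 and 2011 ± 415 CPM. Mitochondrial genes took 5.76 ± 1.06% of reads in heterozygotes and 7.16 ± 0.51% in knockouts (exact permutation p = 0.1, the smallest possible). Mitochondrial ribosomal RNA took 0.246 ± 0.0566% and 0.428 ± 0.101%, and total reads were 13530229 to 14768224 and 15426713 to 15993564 (exact permutation p = 0.1 each). Immediate early and heat shock genes were positive in 20 of 25 (0.16, 0.00359), glycolysis and hypoxia genes in 20 of 25 (0.08, 0.0253), astrocyte markers in 14 of 18 (0.11, 0.0321) and sex-linked genes in 4 of 5 (0.32, 0.0345). With an estimated correlation the 4 calls were lost, at adjusted p = 0.520, 0.640, 0.803 and 0.520. The sex-linked list joins Xist, with a log2 fold change of -1.01, and 4 Y-linked genes, which were positive. These mark opposite sexes, so 1 direction for that list cannot be read as an effect of genotype. Dnajb1, a heat shock cochaperone gene, had 49.2 ± 3.71 and 63.3 ± 9.19 CPM.

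Among single genes with the lowest p, Hddc3 had a log2 fold change of 0.67 ± 0.16, Rapgef4 of 0.61 ± 0.15, Sox7 of 0.70 ± 0.18 and the pseudogene Gm14121 of 0.88 ± 0.19. Lum, a matrix proteoglycan gene, stood at -0.74 ± 0.17, Rreb1 at -0.49 ± 0.12, Pear1 at -0.76 ± 0.19 and Gm10800 at -1.82 ± 0.40. By edgeR, 0 genes were higher and 0 lower among 15468 tested, with a lowest adjusted p of 0.930. An unadjusted p under 0.05 was found for 593 genes, 263 higher and 330 lower. That count was 1352 without knockout library 10, 389 (60 higher) without knockout library 12 and 548 (97 higher) without knockout library 8. It was 1206 with the mural score as a covariate, 895 (480 higher) with the sex term, 943 by limma-voom and 284 (68 higher) in the fit of all 12 libraries. Upper-quartile scaling gave 171 higher and 382 lower, and a filter of 5 CPM gave 106 and 355. DESeq2 called 0 higher and 1 lower, which was Gm10800, and the authors' table listed the same gene alone. Limma-voom called 0 and 0. Groups did not overlap for 1830 genes, or 11.8%, where chance gives 10%.

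Of the 28 lists, 9 were called lower and 5 higher by camera, and 0 kept the call with an estimated correlation (adjusted p = 0.319 to 0.803) or by fry (lowest adjusted p = 0.402). Without heterozygous library 2 the camera adjusted p was 0.155 for pan-reactive, 0.433 for A1, 0.106 for A2, 0.0632 for matrix, 0.0745 for NF-kappaB, 0.953 for cytokine and 0.568 for sex-linked genes. Without heterozygous library 6 endothelial and mural markers turned positive (0.449), and the adjusted p was 0.259 for astrocyte markers, 0.264 for immediate early and 0.449 for glycolysis genes. Without knockout library 8 it was 0.0633 for astrocyte markers and 0.317 for glycolysis genes. Without knockout library 10 it was 0.123 for sex-linked, 0.0504 for mural, 0.761 for cytokine, 0.0799 for A1, 0.0781 for glycolysis and 0.0522 for matrix genes. Without knockout library 12 astrocyte markers turned negative (0.891), and cytokine genes stood at 0.0743 and A1 genes at 0.183.

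Other settings ended list calls in the astrocyte fraction as well. With the mural score of 5 genes as a covariate, chosen after the data were seen, cytokine genes turned positive (camera adjusted p = 0.000906). The adjusted p was then 0.808 for pan-reactive, 0.314 for A1, 0.972 for A2, 0.685 for matrix, 0.423 for NF-kappaB, 0.0876 for immediate early, 0.239 for glycolysis and 0.613 for sex-linked genes, and 0.101 for astrocyte markers. With the score of all 18 endothelial and mural markers instead, matrix and pan-reactive genes stood at 0.00106 each. In 1 fit of all 12 libraries it was 0.0613 for pan-reactive, 0.161 for A1, 0.115 for cytokine, 0.0560 for glycolysis and sex-linked genes, 0.121 for astrocyte and 0.114 for mural markers. Cytokine genes stood at 0.0848 with the sex term and 0.0624 with no filter, A1 genes at 0.0812 with no filter, and sex-linked genes at 0.891 with DESeq2. Astrocyte markers stood at 0.155 with 1 surrogate variable, and with a filter of 5 CPM they stood at 0.0697 and glycolysis genes at 0.0862.

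The other 14 lists did not pass. Camera adjusted p was 0.0601 for neutrophil, 0.224 for microglia, 0.559 for monocyte, 0.599 for lymphocyte, 0.350 for neuron, 0.189 for oligodendrocyte and 0.814 for oligodendrocyte precursor markers. It was 0.0898 for interferon-stimulated, 0.135 for disease-associated microglia, 0.372 for cholesterol, 0.599 for alternative activation, 0.814 for proliferation, 0.979 for MHC class II genes and 0.816 for genes around Sema4b. The alternative activation list had a median of 0.01 with a negative mean and test, and the list around Sema4b a negative median with a positive test. The border macrophage list had 4 tested members and was not tested.

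**Figure D3:**
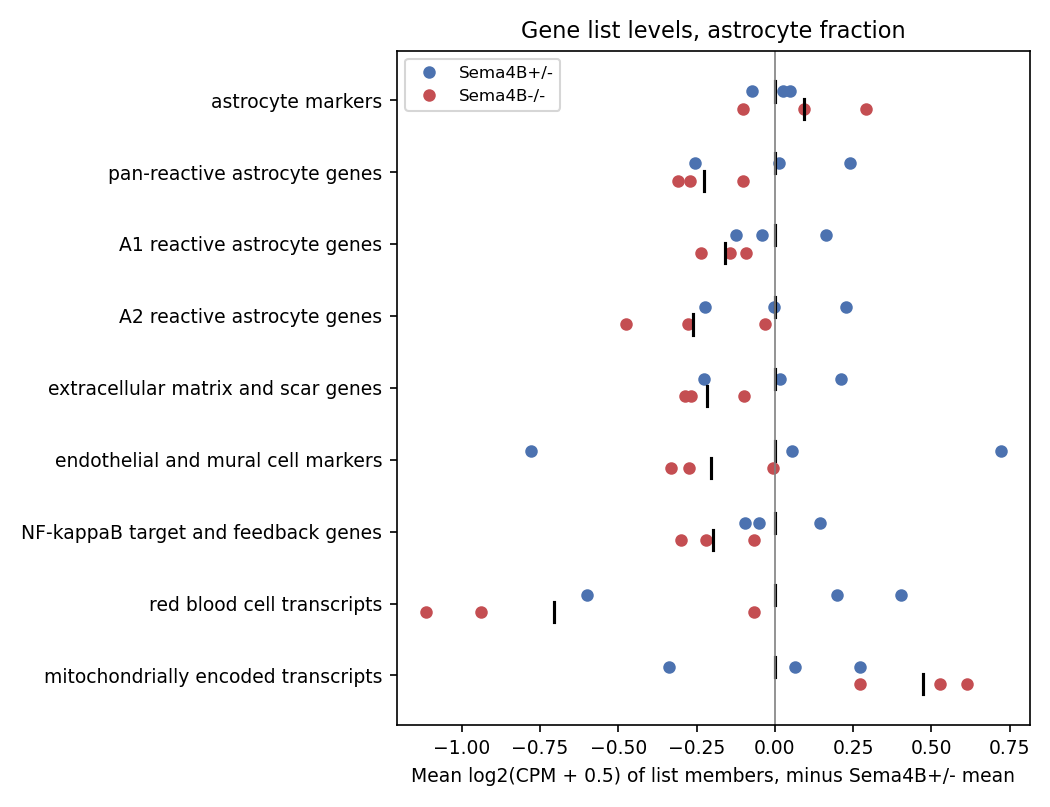
Mean log2(CPM + 0.5) of each list's members per astrocyte library (horizontal axis, relative to the heterozygous mean), with dots for libraries and black ticks for group means of 3 libraries. The reactive, matrix and NF-kappaB lists had lower means in knockouts, with overlap between the groups, and heterozygous libraries were widely spread for endothelial and mural markers.

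The test of the difference between fractions asks whether the genotype acted differently on the 2 cell populations. Fry, Il34 and Cacna1c had the lowest p among genes with higher means in knockout immune libraries and lower means in knockout astrocyte libraries. Il34, which encodes a ligand of the microglial receptor Csf1r, had 11.2 ± 1.08 and 20.5 ± 2.54 CPM in the immune fraction and 33.4 ± 1.91 and 28.5 ± 1.55 CPM in the astrocyte fraction. Neuron markers also had positive fold changes in the immune fraction (median log2 fold change 0.58). Whether the differences of these genes between the fractions followed neuron RNA was not tested. The log2 difference of the effects, astrocyte minus immune, was -1.13 ± 0.20 for Fry, -1.10 ± 0.20 for Il34, -1.51 ± 0.31 for Cacna1c, -0.97 ± 0.21 for Ablim1 and -1.07 ± 0.23 for Slc4a8. It was 1.03 ± 0.22 for Rps10, 1.04 ± 0.24 for Snhg12, 1.31 ± 0.32 for Sowahc, 1.39 ± 0.35 for Arhgap9 and 0.98 ± 0.25 for Npl. By edgeR 0 genes were higher and 0 lower among 16880 (lowest adjusted p = 0.475), 1753 had an unadjusted p under 0.05 (1073 without heterozygous immune library 1, 1081 without knockout astrocyte library 8 and 1107 without knockout astrocyte library 12), and DESeq2 called 0 higher and 3 lower, which were Fry, Il34 and Cacna1c.

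Sex-linked transcripts differed between libraries within groups. Xist ranged from 0.541 to 776 CPM in the immune libraries, and the 4 Y-linked genes summed from 0 to 184 CPM. Heterozygous libraries of neighbouring column numbers were alike across the fractions, with Y-linked levels of 184 and 207 CPM in libraries 3 and 4 and 32.8 and 29.9 CPM in libraries 5 and 6. Some libraries held both kinds, with 565 CPM of Xist and 29.9 CPM of Y-linked genes in heterozygous astrocyte library 6. The labels do not say whether such a library pooled animals of both sexes, so the number of animals behind each group is not known.

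**Figure D4:**
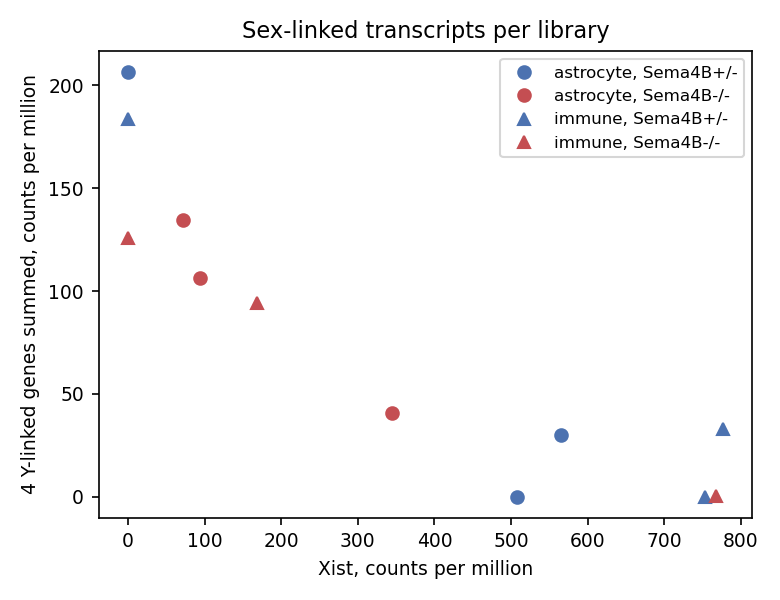
Xist (horizontal axis, CPM) against the sum of 4 Y-linked genes (vertical axis, CPM), 1 point per library, with colour for genotype and shape for fraction. Libraries of each group were spread along both axes, and several held both kinds of transcript.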

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

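Of the tests below, the pseudocounts of 0.1 and 5 CPM, the score of all 18 endothelial and mural markers, the limit to genes tested in both fractions and those of RNA from other brain cells, of inflammatory genes relative to microglia markers and of genes near Sema4b were chosen after the results were seen, and the limits of 2 and 4 standard errors were set after the list medians were known. The tests of sex, of mural cells and of other splits were written before their results. The mural score of 5 genes and the sex term for lists, on which they rest, were however chosen after the data were seen. Camera on the interaction term, at the preset correlation, called a difference of the genotype effect between the fractions in 15 lists, and 0 of these calls held with an estimated correlation (lowest adjusted p = 0.783).

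The median of the difference, astrocyte minus immune on the log2 scale, was 0.60 for immediate early and heat shock genes, 0.69 for microglia markers, 0.98 for monocyte markers, 0.76 for border macrophage markers and 0.61 for neutrophil markers. It was 0.52 for disease-associated microglia genes, 0.31 for NF-kappaB genes, 0.42 for alternative activation genes, 0.54 for MHC class II genes and 0.42 for mitochondrially encoded transcripts. It was -0.58 for neuron markers, -1.27 for endothelial and mural markers, -0.59 for semaphorin and plexin genes, -0.21 for cholesterol genes and -0.47 for matrix genes. Adjusted p ran from 1.57e-06 to 0.0356, and with an estimated correlation from 0.783 to 0.849. Of these members only 7 of 14 monocyte, 4 of 12 border macrophage, 10 of 17 neutrophil, 13 of 19 alternative activation and 9 of 12 MHC class II genes passed the count filter of both fractions. With genes tested in both fractions the camera adjusted p was 0.00374 for monocyte and 0.0476 for neutrophil markers, 0.0635 for alternative activation and 0.0589 for MHC class II genes, whose calls were lost, and border macrophage markers had too few members for the test. With an estimated correlation 0 calls held (lowest adjusted p = 0.846).

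The lower myeloid and inflammatory lists of the knockout immune libraries may reflect a larger share of RNA from other brain cells. Group means of the neuron, astrocyte, oligodendrocyte and vessel scores were higher and those of the 4 myeloid lists lower. Lists of a kind differed in their change by at most 1.21 standard errors, within the limit of 2, but by 2.46 with a pseudocount of 5 CPM in place of 0.5. For neuron against vessel scores the standard error was 1.02 on the log2 scale, so large differences could stay within the limit. The explanation by RNA from other brain cells stays open. Knockout library 11 departed from it, with scores relative to the heterozygous mean of 1.02 for neuron, -0.65 for astrocyte, -0.76 for vessel and -0.11 for oligodendrocyte markers, and without knockout library 9 the oligodendrocyte list, not called with all libraries, turned negative (adjusted p = 0.788). Relative to the microglia score, the cytokine and NF-kappaB score differed by 0.16 ± 0.20 (interval of 2 standard errors -0.25 to 0.57), which did not exclude the decrease of 0.23 set as the limit, while -0.19 to 0.54 with a pseudocount of 5 CPM did, so the outcome depends on the pseudocount and a loss of inflammatory transcription relative to microglia markers stays open. With the Y-linked level as a covariate 10 of the 10 lists stayed lower and past the camera threshold at the preset correlation. That level was 72.1 ± 97.9 CPM in heterozygous and 73.5 ± 65.5 CPM in knockout libraries, with a correlation with genotype of 0.0098. A covariate so alike between the genotypes could move the fold changes of these lists little, so the test decides nothing beyond this balance.

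The lower matrix, mural and pan-reactive lists of the knockout astrocyte libraries may follow the number of mural cells. With the mural score of 5 genes as a covariate, 0 of the 2 lists of matrix and pan-reactive genes stayed past the threshold, their medians went from -0.30 to -0.03 and from -0.24 to 0.02, and genotype accounted for 0.457 of the variance of that score. With the score of all 18 endothelial and mural markers in its place, the 2 lists stayed lower and past the threshold (camera adjusted p = 0.00106 each). That score also holds endothelial genes and had a correlation of 0.726 with the score of 5 genes. Genotype accounted for 0.0493 of its variance, so it could move these fold changes little, and its outcome decides nothing. The explanation by mural cells stays open. With the sex term 3 of the 3 lists stayed lower and past the threshold. The Y-linked level had a correlation of 0.106 with genotype in these libraries. The sex term could therefore move the fold changes of these lists little, and its test decides nothing. A change of the astrocytes themselves was not separated from the number of mural cells.

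Hddc3, 116.6 kb from Sema4b, had positive fold changes in both fractions, 0.67 ± 0.16 in astrocyte and 0.87 ± 0.34 in immune libraries, and may belong to a region altered with the gene. Of 62 genes within 2 Mb of Sema4b, 12 (19.4%, 95% interval 10.4 to 31.4%) had an unadjusted p under 0.05 in at least 1 fraction, against 18.0% of other genes (one-sided Fisher exact p = 0.439). If a variant region of another strain acted alike in both fractions, which was not tested, such genes would be more frequent there, and 2 of the 62 genes (3.23%), Hddc3 and Fam103a1, had an unadjusted p under 0.1 with 1 direction in both, against 0.871% of others (one-sided Fisher exact p = 0.104). Hddc3, the gene that prompted these tests, was counted in both, which raised the shares near Sema4b. Neither test separated the explanations.

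Of the 10 splits of the 6 immune libraries, 1, the real one, gave as many as its 2284 genes at an unadjusted p under 0.05, and the highest other gave 1980. Of the 10 splits of the astrocyte libraries 8 gave as many as the real 593, with 1606 the highest other. Of the 10 splits of the heterozygous libraries between fractions 1 gave as many as 10171 genes past the threshold, and the highest other gave 0. With 10 splits a share under 0.05 cannot be reached. For the difference between fractions 10 of 100 splits, drawn at random with the real one, gave as many as 1753 genes, with 3103 the highest other, so chance could not be excluded.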

How the results depend on the processing

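The covariates of neuron and mural scores and of the whole endothelial and mural list, the limit of lists to genes tested in both fractions, the scaling to microglia markers, DESeq2 without independent filtering and the sex term for lists were chosen after the data were seen, and all other settings before. No paired analysis was run because the groups share no replicate number in the labels and no label links libraries of the fractions to an animal. In heterozygotes the sex-linked levels of neighbouring column numbers were alike across the fractions. Y-linked genes and Xist had 0 and 753 CPM in library 1 and 0 and 508 in library 2, 184 and 0.541 in 3 and 207 and 0.648 in 4, and 32.8 and 776 in 5 and 29.9 and 565 in 6. In knockouts they were 0.0661 and 768 in 7 and 40.5 and 344 in 8, 94.3 and 169 in 9 and 134 and 71.8 in 10, and 126 and 0.614 in 11 and 107 and 93.7 in 12, so Xist differed more between neighbours there. The heterozygous levels are a hint from the data that fractions may share animals, and this was not used to pair them. The comparison of fractions, the difference between them and their splits treated libraries as independent, so their p-values leave out any such sharing. The gene tests used raw counts and no pseudocount. For the list scores, pseudocounts of 0.1 and 5 CPM in place of 0.5 were chosen after the data were seen. The largest difference of change between lists was then 1.25 and 2.46 standard errors against 1.21, and the relative inflammatory score 0.15 (-0.28 to 0.57) and 0.17 (-0.19 to 0.54) against 0.16 (-0.25 to 0.57). With the mural score of 5 genes as a covariate 0 of the 2 lists of matrix and pan-reactive genes stayed past the threshold at each pseudocount, and with the score of all 18 endothelial and mural markers the 2 stayed (adjusted p = 0.00106 each), and with the neuron score the genes at an unadjusted p under 0.05 numbered 823 and 875 against 830. Where leaving out a library left 2 in a group, edgeR pooled the spread over genes. Within each fraction the counts of genes past the threshold were 0 higher and 0 lower under the other scalings, filters, thresholds and covariates, in 1 fit of all 12 libraries and without each library, except as follows. For the difference between fractions RLE scaling, a filter of 5 CPM and leaving out each library were run with edgeR, and gave 0 and 0. In the immune fraction DESeq2 called 378 higher and 68 lower, and without independent filtering 283 and 41. Scaling to microglia markers gave 1112 higher and 0 lower, and moved the median of all genes by 0.62 on the log2 scale. In the astrocyte fraction DESeq2 called 1 lower, with or without independent filtering, and for the difference between fractions it called 3 lower. Unadjusted p under 0.05 was found by edgeR for 2284 immune and 593 astrocyte genes and for 1753 in the difference, and limma-voom called 0 in each fraction. In the simulation 44.5% of immune genes changed 2-fold were recovered beside 9 false calls. Its changed genes lay above a minimum mean read count, so recovery among genes with few reads was not measured. Within the fractions every list call was lost with an estimated correlation and with fry, and fry was not run for the difference between them. The neuron list under the neuron covariate and the mural list under the mural covariate share genes with their covariate, as the microglia list does with the scaling to its members, so their change there followed from the construction and decides nothing. The neuron score also lay higher in every knockout immune library, so the other changes under that covariate decide nothing either. The cause was not tested for any change of count or direction.

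Directions turned for the following. With 1 surrogate variable in the immune fraction, the adjusted p was 0.873 for mitochondrially encoded transcripts. With 1 surrogate variable in the astrocyte fraction, the adjusted p was 0.796 for genes around Sema4b and 0.955 for homeostatic microglia markers. With a filter of 5 CPM in 3 libraries in the immune fraction, the adjusted p was 0.898 for extracellular matrix and scar genes. With a filter of 5 CPM in 3 libraries in the astrocyte fraction, the adjusted p was 0.903 for oligodendrocyte precursor markers and 0.834 for proliferation genes. In 1 fit of all 12 libraries in the immune fraction, the adjusted p was 0.840 for sex-linked genes. In 1 fit of all 12 libraries in the astrocyte fraction, the adjusted p was 0.390 for lymphocyte markers, 0.933 for oligodendrocyte precursor markers, 0.810 for alternative activation genes and 0.810 for MHC class II. With RLE scaling in the astrocyte fraction, the adjusted p was 0.976 for MHC class II. With upper-quartile scaling in the astrocyte fraction, the adjusted p was 0.948 for MHC class II. With fry in the immune fraction, the adjusted p was 0.990 for sex-linked genes. With limma-voom in the immune fraction, the adjusted p was 0.840 for sex-linked genes, 0.840 for lymphocyte markers, 0.402 for red blood cell transcripts, 0.190 for mitochondrially encoded transcripts, 0.363 for interferon-stimulated genes, 0.363 for pan-reactive astrocyte genes, 0.840 for A1 reactive astrocyte genes and 0.474 for glycolysis and hypoxia genes, and the log2 fold change was 0.10 for Xist, 0.36 for Uty, 0.21 for Hba-a2, 0.37 for Hba-a1, 0.079 for mt-Rnr2 and 0.096 for mt-Nd6. With limma-voom in the astrocyte fraction, the adjusted p was 0.986 for genes around Sema4b, 0.319 for proliferation genes and 0.206 for cholesterol synthesis genes. With the mural score as covariate in the astrocyte fraction, the adjusted p was 0.685 for neutrophil markers, 0.0158 for endothelial and mural cell markers, 0.0543 for oligodendrocyte precursor markers, 0.000906 for inflammatory cytokines and chemokines, 0.0634 for alternative activation genes and 0.0876 for MHC class II, and the log2 fold change was 3.27 for Xist, -0.78 for Kdm5d, -1.01 for Uty, -1.15 for Ddx3y, 0.073 for Kcnj8, 0.15 for Cspg4, 0.25 for Tnf, 0.025 for Il4ra and 0.12 for S1pr3. With the neuron score as covariate in the immune fraction, the adjusted p was 0.104 for lymphocyte markers, 0.996 for neuron markers, 0.0122 for red blood cell transcripts, 0.00142 for mitochondrially encoded transcripts, 0.0457 for inflammatory cytokines and chemokines, 0.615 for NF-kappaB target and feedback genes, 3.02e-06 for interferon-stimulated genes, 0.0896 for disease-associated microglia genes, 0.497 for alternative activation genes, 0.00783 for pan-reactive astrocyte genes, 0.134 for A1 reactive astrocyte genes, 0.529 for A2 reactive astrocyte genes, 0.611 for proliferation genes and 0.247 for glycolysis and hypoxia genes, and the log2 fold change was 1.55 for Xist, 0.59 for Hba-a2, 0.77 for Hba-a1, 0.31 for mt-Rnr2 and 0.30 for mt-Nd6. With no filter beyond 1 read in the astrocyte fraction, the adjusted p was 0.525 for lymphocyte markers, 0.755 for alternative activation genes, 0.902 for MHC class II and 0.987 for proliferation genes. Scaled to microglia markers in the immune fraction, the adjusted p was 0.485 for mitochondrially encoded transcripts, 0.963 for glycolysis and hypoxia genes and 0.886 for extracellular matrix and scar genes, and the log2 fold change was 0.46 for Uty, 0.28 for Ighm, 0.13 for Hba-a2, 0.27 for Hba-a1, 0.45 for mt-Rnr2, 0.49 for mt-Nd6, 0.12 for Birc3, 0.13 for Trem2, 0.11 for Ctsd, 0.023 for Il4ra, 0.18 for H2-DMb1, 0.053 for Cd80, 0.32 for H2-DMa, 0.050 for Srgn, 0.042 for Mcm2 and 0.18 for Mcm6. With the sex term in the immune fraction, the log2 fold change was 0.53 for Xist and 0.28 for Uty. With the sex term in the astrocyte fraction, the adjusted p was 0.824 for oligodendrocyte precursor markers and 0.651 for MHC class II, and the log2 fold change was 1.37 for Xist.

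In the immune fraction the leave-one-out adjusted p of lists ran from 0.0241 to 0.504 for A1 reactive astrocyte genes, 3.20e-06 to 0.982 for extracellular matrix and scar genes, 0.296 to 0.971 for glycolysis and hypoxia genes, 1.56e-07 to 0.398 for interferon-stimulated genes, 0.138 to 0.869 for lymphocyte markers, 0.193 to 0.869 for mitochondrially encoded transcripts, 0.000329 to 0.788 for oligodendrocyte markers, 0.000320 to 0.875 for oligodendrocyte precursor markers, 0.00209 to 0.732 for pan-reactive astrocyte genes, 0.00706 to 0.726 for red blood cell transcripts and 0.138 to 0.782 for sex-linked genes. In the immune fraction the leave-one-out log2 fold change of genes ran from -1.07 to 0.33 for Hba-a1, -1.03 to 0.19 for Hba-a2, -0.68 to 1.95 for Uty, -0.33 to 0.037 for mt-Nd6 and -0.39 to 0.031 for mt-Rnr2. In the astrocyte fraction the leave-one-out adjusted p of lists ran from 0.0368 to 0.981 for alternative activation genes, 0.0683 to 0.984 for MHC class II, 0.000227 to 0.891 for astrocyte markers, 0.00367 to 0.904 for cholesterol synthesis genes, 0.00418 to 0.984 for disease-associated microglia genes, 2.87e-18 to 0.449 for endothelial and mural cell markers, 0.277 to 0.984 for genes around Sema4b, 3.19e-05 to 0.817 for homeostatic microglia markers, 0.00433 to 0.893 for interferon-stimulated genes, 0.249 to 0.997 for lymphocyte markers, 0.185 to 0.893 for monocyte-derived cell markers, 3.67e-09 to 0.891 for neuron markers, 1.43e-06 to 0.724 for oligodendrocyte markers, 0.00587 to 0.893 for oligodendrocyte precursor markers and 0.189 to 0.893 for proliferation genes. In the astrocyte fraction the leave-one-out log2 fold change of genes ran from -0.046 to 0.48 for Aspa, -0.30 to 3.07 for Ddx3y, -0.0070 to 0.89 for F13a1, -0.035 to 2.53 for Kdm5d, -0.79 to 0.047 for Neu4 and -0.14 to 2.62 for Uty.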

Other observations

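Genotype fold changes were compared between the fractions gene by gene. Across the 14413 genes tested in both, fold changes had a Pearson r of -0.05, where genes are not independent replicates. At an unadjusted p under 0.05 in both, 23 genes were lower in both fractions, against 12.3 for independent lists, and 5 were higher in both, against 26.5. Another 36 moved in opposite directions, for which no number under independent lists was computed, so they are read neither as many nor as few. These genes were chosen after their values were seen.

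Gm14121, a processed pseudogene on chromosome 2, had log2 fold changes of 0.88 ± 0.19 in astrocyte and 0.91 ± 0.32 in immune libraries. It shared 908 of its 1350 words of 31 bases (67.3%) with Btbd1, a gene on chromosome 7, 1565.5 kb from Sema4b, so its reads are uncertain. Btbd1 had log2 fold changes of 0.09 and -0.01. Gm10800 was lower in both fractions, at -1.82 ± 0.40 and -2.19 ± 0.43, and shared 25.4% of its words with Gm26870 and 25.2% with Gm10801.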
